A study of Homo sapiens
Mus musculus with 18 samples.

How the data were processed

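RNA had been taken from snap-frozen pieces of PC3 xenograft tumours, 9 from mice treated with TGH and 9 from mice treated with vehicle, with an RNA integrity number of at least 7 per the labels' protocols. Per the labels, ribosomal RNA was depleted, with both RiboMinus and Ribo-Zero named, and directional libraries were made with a Nextflex kit. Total RNA was the input, so transcripts without a poly(A) tail can be present. The authors deposited raw counts of reads per gene in 1 human and 1 mouse table, each with a column for every tumour. The counts are whole numbers whose sums differ between columns. The submitters' processing notes name the genome builds hg19 and mm10. The aligner, the counting tool, its use of strand and the way reads were divided between the species are not given in the sources used here. No coordinates are printed, because the gene table used for older symbols is of another build than hg19. Columns were matched to tumours by the numbers in their names, and replicate numbers are those of the labels, which differ between the arms and pair no samples.

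Each table was analysed on its own counts with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr (14792 of 23710 human and 12345 of 24421 mouse rows), libraries scaled by TMM, and TGH compared with vehicle by the quasi-likelihood F test on all 18 libraries without covariates. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Log2 fold changes are given with standard errors derived from the F statistic, and levels as CPM with TMM scaling, mean ± SD over libraries. Gene lists (33 human and 26 mouse, covering metabolism, stress, proliferation and cell types) were written before the data were examined, as were the main design, the gene naming rule and most alternatives. Of 646 human list entries 631 were found, 37 of them by an older symbol, and of 461 mouse entries 456. The 30 human and 20 mouse lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. A list score is the mean over members of log2 CPM centred per gene, and was compared by exact two-sided permutation over all 48620 splits. The same test served for shares and totals of libraries. Neither table holds mitochondrially encoded genes, so their share was left out.

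The genes named are, per table, the 10 largest called changes in each direction at a mean of at least 5 CPM with a regular symbol, up to 4 members with the smallest p in each called list, and a fixed set that includes the glucose transporters and markers of host cells. A gene that this rule takes is not reported here. CA9, NDRG1, DDIT4 and HIST1H4C and the mouse gene Krt19 were named after their values were seen. Adipoq, with 233 counts over all libraries, and Krt8 in mouse and CYP1A1 in human were too low to test.

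Counts were simulated with the means, library sizes and edgeR dispersions of the human table, each gene drawn independently. Among 14792 genes, 200 with a mean of at least 5 CPM were changed, and 23 members of the glycolysis list were shifted by 0.75 log2 besides. Of the 200, edgeR recovered 31.3% of genes changed 1.5-fold, 89.6% of those changed 2-fold and all changed 4-fold. Its 171 calls, shifted list members included, held 8 unchanged genes. In the mouse table, with 12345 genes and 24 members of the matrix list shifted, it recovered 14.9%, 70.1% and 95.5%, with 5 unchanged genes among 143 calls. DESeq2 made 26 of its 203 human calls and 14 of its 162 mouse calls in unchanged genes (12.8% and 8.64%). The tables differ in depth and in common biological coefficient of variation (0.321 human, 0.379 mouse), and the simulations do not separate the 2.

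Alternatives were DESeq2 1.42.0, RLE size factors, limma-voom with and without sample weights, other filters, library sizes of human plus mouse counts, the mouse share as a covariate, 1 surrogate variable from sva 3.50.0, and each library left out. Chosen after seeing the data were the Rn45s level as a covariate, the fit without vehicle 16, 18 and 19, counts thinned to equal depth, and the mouse table without Rn45s and Lars2. Covariate-adjusted score differences were tested by Freedman-Lane permutation (100000 draws), and correlations within an arm by all 362880 pairings. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.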

Results

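Gene expression was measured by RNA sequencing in 18 xenograft tumours grown from PC3, an established human prostate cancer cell line that grows without androgen, in athymic nude mice, which have few mature T cells. Tumour cells had been injected into both hind flanks, and mice in 2 arms of 10 received daily intraperitoneal injections of vehicle or of trans-Gnetin H (TGH) at 150 mg/kg. TGH is a trimer of resveratrol, a plant stilbene, and the question named in the title of the series is whether it deprives prostate cancer cells of glucose. Each arm gave 9 libraries, TGH 1 to 7, 9 and 10 and vehicle 11 to 16 and 18 to 20. Every tumour was deposited as counts of human genes, which report on the tumour cells, and counts of mouse genes, which report on the host cells in the same piece of tissue. Human totals ran from 9928972 counts in vehicle 18 to 29256180 in TGH 4, and mouse totals from 2348987 in vehicle 20 to 7563228 in TGH 2. The labels do not say which tumours shared a mouse, so the p-values measure the spread between these 18 samples.

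The 2 tables separated the species well for epithelial and immune genes. KRT8, a keratin of epithelial cells, had 184599 human counts over all libraries against 26 counts for mouse Krt8. Conversely, Csf1r, the receptor that marks macrophages, had 48894 mouse counts against 429 human ones. COL1A1, the main chain of type I collagen, had 50503 human counts and 914648 mouse counts, so that 94.8% of the reads of this gene pair were mouse. No pair of libraries within an arm agreed within sampling noise. The lowest chi-square per degree of freedom was 17.6 in the human table, between TGH 5 and TGH 6, and 8.37 in the mouse table, between TGH 1 and TGH 3.

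The first comparison asked which genes of the tumour cells differed between TGH and vehicle. The glucose transporter SLC2A1 rose by 1.11 ± 0.20 (log2 fold change ± SE), from 79.8 ± 27.1 CPM (scaled counts per library total; mean ± SD, n = 9) in vehicle to 172 ± 47.5 in TGH, and was above the vehicle median in all 9 TGH libraries (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0183). Genes that respond to low oxygen rose with it, among them EGLN3, a HIF prolyl hydroxylase (1.16 ± 0.25), and the collagen prolyl hydroxylase subunits P4HA1 (0.66 ± 0.14) and P4HA2 (0.66 ± 0.13). In the other direction RPPH1, the RNA component of nuclear RNase P, fell by 2.42 ± 0.47 on the log2 scale, and the metallothionein MT2A, a metal-binding protein, fell by 1.29 ± 0.28. MT2A stood at 2286 to 2456 CPM in vehicle 16, 18 and 19 and at 539 to 1035 CPM in the other vehicle libraries, and without those 3 its log2 fold change was -0.57 ± 0.17 (edgeR adjusted p = 0.100). In total 30 of 14792 tested human genes were higher and 31 were lower with TGH.

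The largest increases were in PADI3, a peptidylarginine deiminase (2.29 ± 0.52), the gap junction proteins GJB2 (1.46 ± 0.29) and GJA1 (1.30 ± 0.24), S100A8, a calcium-binding alarmin (1.45 ± 0.30), and HAS2, which makes hyaluronan (1.45 ± 0.22). IGFBP3, a binding protein of insulin-like growth factors (1.40 ± 0.24), AKR1B10, an aldo-keto reductase (1.28 ± 0.29), and PRDM1, a transcriptional repressor (1.23 ± 0.28), also rose. GJB2 went from 200 ± 84.8 to 551 ± 272 CPM and HAS2 from 66.7 ± 18.3 to 182 ± 78.1. Among the decreases, RPS10, a ribosomal protein, fell by 2.20 ± 0.49 on the log2 scale (190 ± 181 CPM in vehicle against 41.4 ± 18.3 in TGH). Its level was 267 to 489 CPM in vehicle 16, 18, 19 and 20, but 34.1 to 57.8 CPM in vehicle 11 to 15, within the range of 24.9 to 82.2 CPM of the TGH libraries, and without vehicle 16, 18 and 19 its log2 fold change was -1.004 (edgeR adjusted p = 0.202). Reads of RPS10 can be shared with pseudogene copies, so its level is uncertain. ZNF587, a zinc finger gene with close relatives, fell by 1.26 ± 0.19 on the log2 scale, KIAA1919 by 1.27 ± 0.23, KCNA7, a potassium channel, by 1.16 ± 0.22, and SLC25A45, a mitochondrial carrier, by 1.06 ± 0.22. NAPRT1, an enzyme of NAD synthesis, fell by 1.02 ± 0.20, UCKL1-AS1 by 0.84 ± 0.17 and MIB2, a ubiquitin ligase, by 0.78 ± 0.16 on the log2 scale. UCKL1-AS1 is an antisense gene, and whether the counting used strand is not given in the sources used here. The adjusted p-values of these genes lay between 0.00337 for ZNF587 and 0.0478 for PADI3 (edgeR). The counts depended on the library covariates: with the level of the mouse rRNA precursor Rn45s as a covariate, edgeR called 3 human genes higher and 0 lower (649 lower at unadjusted p below 0.05), while DESeq2 without it called 143 and 227. Of the 22 called genes named here 0 passed with that covariate, although all 22 kept their sign: the median fold change was 0.939 times that without it, and the median SE 1.72 times. PADI3 stood at 2.10 ± 0.92 and SLC2A1 at 1.40 ± 0.34, while RPPH1 stood at -0.68 ± 0.53 and SLC25A45 at -0.49 ± 0.33. Without vehicle 16, 18 and 19, the libraries with the fewest human counts, 36 genes were higher and 96 lower. Besides MT2A and RPS10, calls just past the threshold were lost for PADI3 (1.99 ± 0.50), AKR1B10 (1.30 ± 0.33), EGLN3 (0.96 ± 0.24), P4HA1 (0.55 ± 0.13) and UCKL1-AS1 (-0.70 ± 0.17), whose fold changes stayed within 1.5 times of those with all libraries (adjusted p from 0.0504 to 0.0633). With the mouse share as a covariate 4 of the 22 were lost, MT2A, RPS10, P4HA1 and UCKL1-AS1 (edgeR adjusted p from 0.0619 to 0.112). Human plus mouse library size lost 5, PADI3, EGLN3, P4HA1, MIB2 and RPS10 (0.0536 to 0.0819), and no filter lost 4, PADI3, AKR1B10, PRDM1 and P4HA1 (0.0507 to 0.0525). In 25 of the 31 genes called lower, vehicle 11 lay nearer to the mean of TGH than to that of the other vehicle libraries. ZNF587, for example, stood at 66.3 CPM in vehicle 11, 143 to 281 CPM in the other vehicle libraries and 46.8 to 90.1 CPM in TGH.

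**Figure D1:**
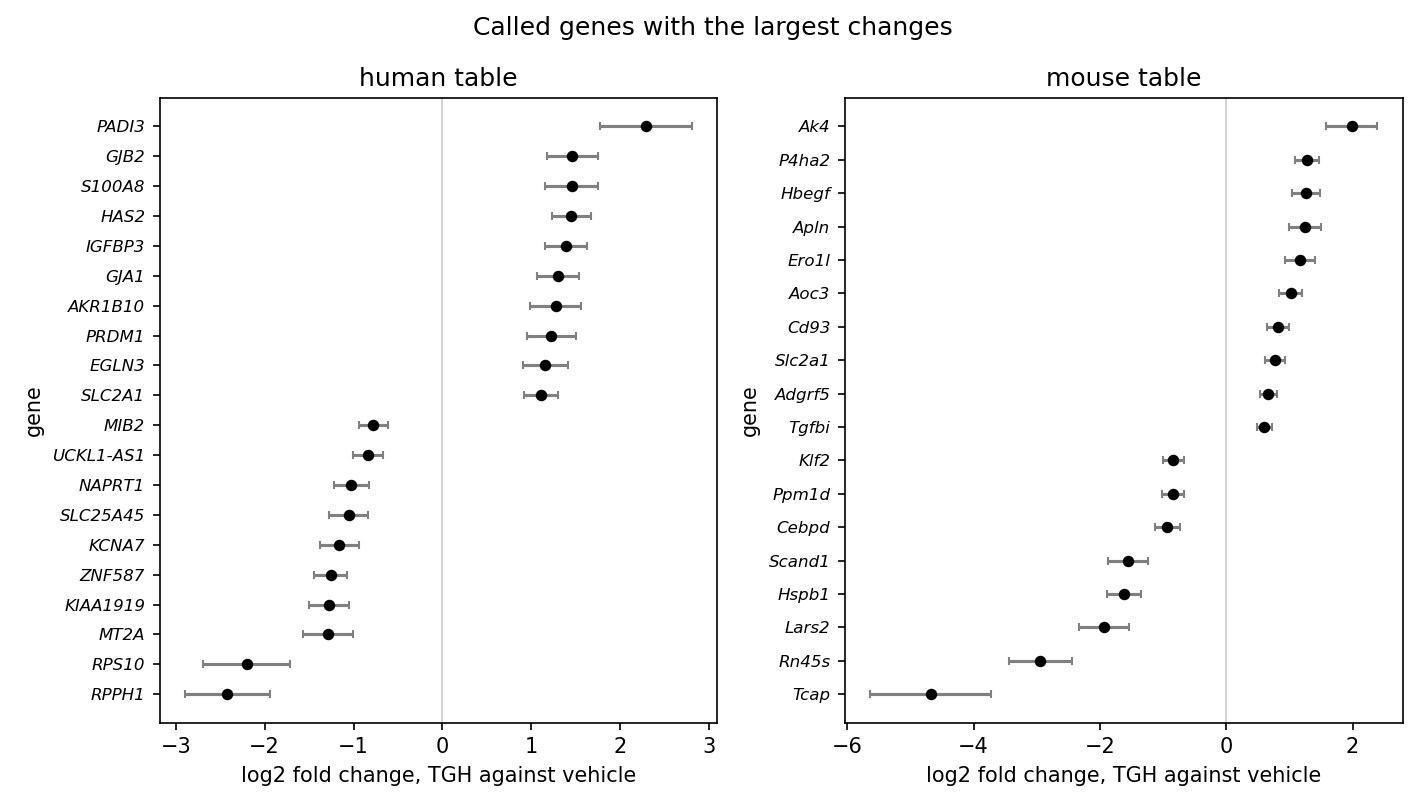
Log2 fold change between TGH and vehicle (x axis, points, with bars of 1 SE) of the called genes with the largest changes (y axis) in the human table (left) and the mouse table (right), 9 libraries per arm. SLC2A1 lies at 1.11 in human and Slc2a1 at 0.78 in mouse, and the lowest points are RPPH1 at -2.42 and Tcap at -4.68.

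Groups of tumour genes were then compared as lists. The hypoxia list, targets of the oxygen-sensing HIF factors, stood higher with TGH than the other genes: 23 of its 24 members had a positive fold change, and the mean over members was 0.52. The list of glucose uptake and glycolysis did likewise, with 22 of 23 members positive and a mean of 0.41. Of the hypoxia list 3 members passed the test over all genes and 7 adjusted over the list alone, which adds CA12 (0.97 ± 0.23) and CA9 (1.07 ± 0.27), carbonic anhydrases, NDRG1 (0.97 ± 0.27) and DDIT4 (0.56 ± 0.17). Of the glycolysis list SLC2A1 alone passed over all genes and 9 members adjusted over the list alone, among them the hexokinase HK2 (0.68 ± 0.17), the fructose bisphosphate regulator PFKFB4 (0.78 ± 0.22) and the phosphoglycerate mutase PGAM1 (0.40 ± 0.12). Camera with a preset correlation of 0.01 gave an adjusted p of 1.53e-09 for hypoxia and 1.58e-07 for glycolysis, whereas both had an adjusted p = 0.352 with an estimated correlation. The list score, the mean centred log2 CPM of the members, was higher with TGH by 0.61 for hypoxia (exact permutation p = 0.00103, two-sided) and by 0.42 for glycolysis (exact permutation p = 0.00144), and all 9 TGH libraries lay above the vehicle median in both. With the Rn45s level as a covariate the glycolysis difference was 0.78 ± 0.13 (SE).

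**Figure D2:**
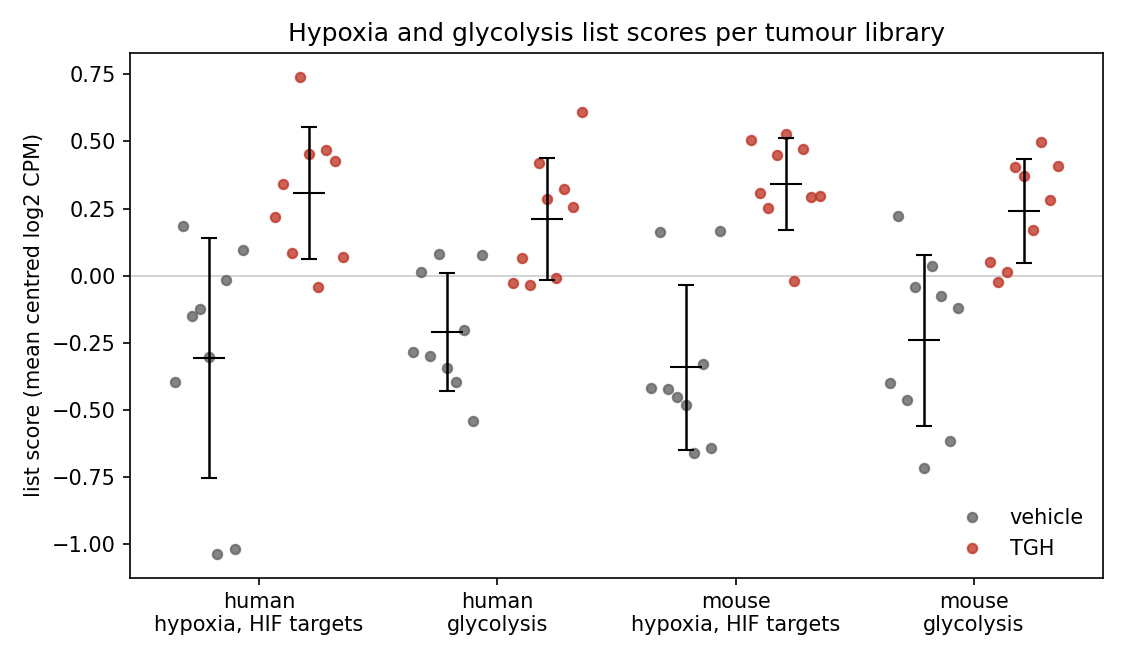
List score (y axis, mean centred log2 CPM over the members of a list) of the hypoxia and glycolysis lists in the human and mouse tables (x axis), 1 point per library, with the mean and SD of the 9 libraries of each arm. The TGH means exceed the vehicle means by 0.61 and 0.42 in the human table and by 0.68 and 0.48 in the mouse table.

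Replication-dependent histones, whose mRNAs end in a stem loop in place of a poly(A) tail, were called lower as a list by camera. Of 14 tested members 12 had a negative fold change, with 0 called over all genes (edgeR quasi-likelihood) and 5 adjusted over the list alone, of which 4 were lower and 1 higher. HIST1H1E fell by 1.87 ± 0.43, HIST2H2AC by 1.68 ± 0.48, HIST2H2BE by 0.83 ± 0.19 and HIST1H2AC by 0.66 ± 0.22 on the log2 scale, while HIST1H4C was the member that rose (1.10 ± 0.41). HIST1H1E, HIST2H2AC and HIST1H4C averaged below 2 CPM. The camera call (adjusted p = 0.00548) had an adjusted p = 0.352 with an estimated correlation and 0.126 with fry. It was also lost with a filter at 1 CPM (mean change -0.39, adjusted p = 0.0536, against a mean of -0.56) and with counts thinned to equal depth (-0.34, adjusted p = 0.165), and with Rn45s as a covariate the list pointed the other way against the remaining genes (adjusted p = 0.906). Rn45s itself, the rRNA precursor, was lower in TGH libraries, at 1.48 ± 1.09% of mouse counts against 10.1 ± 7.77% in vehicle (n = 9 each, exact permutation p = 0.000411).

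Camera called no other human list of the 30 tested. The lysosome and autophagy list, with 14 positive and 9 negative members (camera adjusted p = 0.397), had an adjusted p = 0.0327 with fry, as did hypoxia and glycolysis. Its score was higher with TGH by 0.11 (exact permutation p = 0.00107). Score p-values, not adjusted over lists, were also low for epithelial and mesenchymal markers (exact permutation p = 0.00535), insulin and FOXO signalling (0.0133) and androgen response (0.0142). The androgen response list had 9 tested members and shares NDRG1 with the hypoxia list, so the 2 scores are not separate. The DNA replication list had 12 positive and 13 negative members (camera adjusted p = 0.673) and the mitosis list 15 and 10 (adjusted p = 0.593), and the proliferation marker MKI67 had a fold change of 0.36 ± 0.17 (edgeR adjusted p = 0.347). Targets of the glucose-sensing factors MondoA and ChREBP gave an adjusted p = 0.216 in camera. TXNIP, their best known target, was above the vehicle median in all 9 TGH libraries with a fold change of 0.43 ± 0.15, and passed adjusted over the list alone but not over all genes (edgeR adjusted p = 0.189). ARRDC4, another such target, stood at 0.34 ± 0.39 (edgeR adjusted p = 0.715). The amino acid response list gave an adjusted p of 0.593, with its member ASNS, asparagine synthetase, at 0.09 ± 0.12, and the stress factor DDIT3 stood at -0.13 ± 0.18. LDHA, lactate dehydrogenase, stood at 0.50 ± 0.16 (edgeR adjusted p = 0.168) and passed adjusted over the glycolysis list alone, and VEGFA, the angiogenic factor, at 0.39 ± 0.16 (adjusted p = 0.270). The transporter SLC2A3 averaged 3.19 CPM and stood at 1.43 ± 0.42 (edgeR adjusted p = 0.124), and SLC2A4 averaged 0.819 CPM and stood at -0.09 ± 0.48. HMOX1, haem oxygenase, stood at 0.60 ± 0.26, HMGCS1 of cholesterol synthesis at 0.22 ± 0.15 and CYP1B1, a target of the aryl hydrocarbon receptor, at 0.68 ± 0.49, and none of these passed (edgeR). CYP1A1 had 18 counts over all libraries and was not tested.

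The next comparison asked which host genes differed. The mouse table showed some of the same changes as the human table: mouse Slc2a1 rose by 0.78 ± 0.16, from 70.3 ± 17.9 to 121 ± 29.6 CPM (n = 9 each, edgeR adjusted p = 0.0494), and P4ha2 rose by 1.28 ± 0.19, from 57.4 ± 21.6 to 139 ± 26.4 CPM (adjusted p = 0.00972). Ero1l, an oxidase of the endoplasmic reticulum (1.16 ± 0.23), Ak4, an adenylate kinase (1.99 ± 0.40), and Apln, the ligand of the apelin receptor made by endothelial tip cells (1.25 ± 0.26), rose as well. Human reads counted as mouse could add to such changes. At the highest leak seen among epithelial genes, 1.76% of human reads, they would make up 10.8% of the mouse counts of Slc2a1, 23.1% of Ero1l and 4.82% of P4ha2. In total 10 of 12345 tested mouse genes were higher and 8 lower. Hbegf, a growth factor (1.26 ± 0.22), the amine oxidase Aoc3 (1.02 ± 0.18), the endothelial genes Cd93 (0.82 ± 0.17) and Adgrf5 (0.66 ± 0.14) and the matrix protein Tgfbi (0.60 ± 0.12) completed the increases. Every one of these 10 genes was above its vehicle median in all 9 TGH libraries. With Rn45s as a covariate 15 of the 18 called mouse genes no longer passed, the median SE being 1.60 times and the median fold change 1.25 times those without it. P4ha2 (1.69 ± 0.30) and Ero1l (1.86 ± 0.36) passed, and Slc2a1 stood at 1.17 ± 0.25 (edgeR adjusted p = 0.0828). Slc2a1 was also lost with the mouse share as a covariate (adjusted p = 0.167), human plus mouse library size (0.435), thinned counts (0.0508) and without Rn45s and Lars2 in the table (0.0527), with fold changes from 0.66 to 0.81. Of the 18 called mouse genes 13 no longer passed with the mouse share as a covariate, 10 with human plus mouse library size and 6 with thinned counts. All 18 kept their sign in each.

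The decreases in the mouse table were led by Tcap, a protein of the muscle sarcomere, which fell by 4.68 ± 0.95 on the log2 scale, and by Rn45s, which fell by 2.94 ± 0.50. The way reads were divided between the species is not given, so the reads of Rn45s may not all come from the host. Lars2, a mitochondrial leucyl-tRNA synthetase whose locus can take up rRNA-like reads, fell by 1.94 ± 0.39, the small heat shock protein Hspb1 fell by 1.62 ± 0.27 and Scand1 fell by 1.55 ± 0.32 on the log2 scale. The transcription factors Cebpd and Klf2 fell by 0.93 ± 0.19 and 0.84 ± 0.16, and the phosphatase Ppm1d by 0.84 ± 0.17. Without vehicle 16, 18 and 19 the log2 fold change was -1.69 ± 0.70 for Tcap (edgeR adjusted p = 0.382), -0.83 ± 0.24 for Scand1 (adjusted p = 0.232) and -1.06 ± 0.17 for Hspb1 (adjusted p = 0.0102). Calls were also lost for Cebpd (-0.63 ± 0.17), Klf2 (-0.70 ± 0.17), Ppm1d (-0.73 ± 0.17), Slc2a1 (0.78 ± 0.18), Ero1l (0.94 ± 0.22), Ak4 (1.62 ± 0.33), Aoc3 (0.84 ± 0.17) and Adgrf5 (0.59 ± 0.15), whose fold changes stayed within 1.5 times of those with all libraries (adjusted p from 0.0556 to 0.194). Most of these adjusted p-values were 0.0494, next to the threshold (edgeR), and the count of mouse genes was easily moved: leaving out 1 library gave from 1 to 19 genes higher and from 0 to 18 lower. Scaling by human plus mouse counts shifted the median of all mouse genes to -0.10 and called 3 genes higher and 20 lower, against 10 and 8 with TMM.

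Host lists repeated the increase in hypoxia and glycolysis genes. In the mouse hypoxia list 22 of 24 members had a positive fold change (mean 0.57), 2 passed over all genes and 12 adjusted over the list alone, including Bnip3 (0.97 ± 0.20), a mitophagy receptor, and Egln1 (0.62 ± 0.14), the main HIF prolyl hydroxylase. This list was called by camera (adjusted p = 6.18e-13) and also had an adjusted p = 0.0183 with an estimated correlation. Its score was higher with TGH by 0.68 (exact permutation p = 0.000288). In the glycolysis list 19 of 22 members were positive (mean 0.38), 1 passed over all genes, and 10 were higher and 1 lower adjusted over the list alone, among them Pgam1 (0.65 ± 0.15), Pfkfb4 (0.67 ± 0.19) and the lactate exporter Slc16a3 (1.09 ± 0.31). Its camera call (adjusted p = 2.29e-09) had an adjusted p = 0.127 with an estimated correlation, and its score differed by 0.48 (exact permutation p = 0.00136), or by 0.81 ± 0.18 (SE) with Rn45s as a covariate. The list of tumour epithelial genes as read in the mouse table, a control for human reads counted as mouse, had 6 of 7 tested members positive and a score higher with TGH by 0.66 (exact permutation p = 0.0149), with 8 of 9 TGH libraries above the vehicle median. It was not called by camera (adjusted p = 0.127) and had an adjusted p = 0.0353 with fry. The keratin Krt19 was the 1 member that passed adjusted over the list alone, at 5.42 ± 2.41 CPM with TGH and 0.937 ± 2.40 with vehicle. The reverse control, mouse stroma markers as read in the human table, had 6 positive and 3 negative members. Its score was higher with TGH by 0.43 (exact permutation p = 0.0333), with 7 of 9 TGH libraries above the vehicle median. Neither camera (adjusted p = 0.550) nor fry (0.220) called it.

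Lists of the matrix and of vessel walls were called higher in the host by camera, but not with an estimated correlation. The list of fibrillar collagen and matrix had 19 of 24 members positive, 0 called over all genes (edgeR) and 12 higher adjusted over the list alone, with fibronectin Fn1 (0.81 ± 0.18) and the collagen cross-linking enzymes Loxl2 (0.69 ± 0.16) and Lox (0.60 ± 0.14) in front, followed by Col6a3 (0.52 ± 0.13). Col1a1 stood at 0.68 ± 0.22 (edgeR adjusted p = 0.214) and was among the 12. Lox also belongs to the hypoxia list, where it passed adjusted over the list alone, so the 2 lists are not separate. The call of the matrix list (camera adjusted p = 7.50e-08) had an adjusted p = 0.127 with an estimated correlation. Pericytes and smooth muscle had 12 of 15 members positive, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00304, and adjusted p = 0.127 with an estimated correlation). Lmod1, an actin nucleator of smooth muscle (1.84 ± 0.50), Ndufa4l2 (0.74 ± 0.24) and calponin Cnn1 (24.5 ± 9.80 CPM with TGH and 12.4 ± 9.18 with vehicle) were the higher ones. Des, the muscle intermediate filament that skeletal fibres also make, fell by 2.70 ± 0.70 on the log2 scale. Much of that fall came from vehicle 16, at 1792 CPM against 8.98 to 279 CPM in the other vehicle libraries. Acta2 stood at 0.35 ± 0.16. The endothelial list had 16 of 22 members positive and Apln called over all genes and adjusted over the list alone (camera adjusted p = 0.0129, and adjusted p = 0.480 with an estimated correlation). Its call, at a mean change of 0.22, was lost without vehicle 11 (mean 0.20, adjusted p = 0.0584) or vehicle 15 (0.18, adjusted p = 0.0736), with the mouse share as a covariate (0.18, adjusted p = 0.0529) and with fry (adjusted p = 0.146). Its members Vwf (0.54 ± 0.18), Pecam1 (0.42 ± 0.15) and Ptprb (0.38 ± 0.16) did not pass.

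Dendritic cell and MHC class II genes had 12 of 14 members positive, with 0 called over all genes (edgeR) and 2 adjusted over the list alone (camera adjusted p = 0.000944, and adjusted p = 0.248 with an estimated correlation). With Rn45s as a covariate the call was lost (adjusted p = 0.0937). The 2 were Ciita, the master regulator of class II genes (1.16 ± 0.31), and the integrin Itgax (0.42 ± 0.14), and H2-Eb1 (0.59 ± 0.28) and Ccr7 (0.74 ± 0.35) did not pass. Lists of other host cells were not called: macrophages had 11 positive and 6 negative members (camera adjusted p = 0.631), fibroblasts 11 and 7 (0.405), monocytes and neutrophils 8 and 10 (0.701) and NK and T cells 7 and 5 (0.224). The macrophage gene Adgre1 stood at 0.03 ± 0.13, the neutrophil gene S100a8 at -0.37 ± 0.32, Cd3e of T cells at -0.75 ± 0.89 and Mki67 at 0.17 ± 0.20, none called by edgeR. The lymphatic list, with 5 of 6 members negative, was called by camera (adjusted p = 0.0401, and adjusted p = 0.480 with an estimated correlation) with 0 members called by edgeR over all genes or adjusted over the list alone. Its members stood at 0.11 ± 0.13 for Pdpn, -0.49 ± 0.34 for Flt4, -0.68 ± 0.50 for Mmrn1 and -0.91 ± 0.54 for Reln. TGH 6 and TGH 10 stood apart, with list scores of -2.65 and -3.23 against -0.46 to 1.07 in the other 7 TGH libraries and -0.48 to 1.02 in vehicle, and Reln had 0 CPM in both. The call was lost without TGH 6 (adjusted p = 0.151) or TGH 10 (0.136), and also without TGH 2 or 9 or vehicle 11, 12, 13, 14 or 20 (0.0530 to 0.116).

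Skeletal muscle genes showed the widest difference in the host. All 16 tested members of the list were lower with TGH, 0 passed over all genes (edgeR) and 15 were lower adjusted over the list alone (camera adjusted p = 1.42e-15, and adjusted p = 0.127 with an estimated correlation). The troponins Tnni2 and Tnnt3 had log2 fold changes of -4.20 ± 0.90 and -3.98 ± 0.92, Tnnc2 of -4.36 ± 1.01, the myosin Myh2 of -3.40 ± 0.81 and creatine kinase Ckm of -4.24 ± 1.09. The list held 1.75% of the mouse counts of vehicle 16, 0.345% of vehicle 19 and 0.275% of vehicle 18, and between 0.00288% and 0.131% of every other library. The score difference was -2.86 (exact permutation p = 0.0102), and -1.74 without those 3 libraries (exact permutation p = 0.0895). Oxidative phosphorylation genes of the host, with 24 of 28 members negative, and cytosolic ribosomal protein genes, with 24 of 27 negative, were called lower by camera (adjusted p = 0.00872 and 0.0366), with 0 members called by edgeR over all genes or adjusted over the list alone. With an estimated correlation their adjusted p was 0.738 for both. The first call was lost without TGH 1 or vehicle 16 or 19 (adjusted p from 0.0501 to 0.199), and the second without TGH 1, 2, 3 or 9 or vehicle 16, 18, 19 or 20 (0.0742 to 0.659). Both were lost with fry (adjusted p = 0.525 and 0.654) and with Rn45s as a covariate (0.142 and 0.585), and the second with thinned counts (0.0531). Without vehicle 16, 18 and 19 their mean changes turned to 0.11 and 0.17. Members of the first list were Uqcrb (-0.70 ± 0.28), Ndufb8 (-0.63 ± 0.29), Cox5a (-0.61 ± 0.24) and Cycs (-0.45 ± 0.22), and of the second Rpl35 (-0.53 ± 0.25), Rpl18 (-0.42 ± 0.21) and Rpl5 (0.33 ± 0.17), none of which passed.

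**Figure D3:**
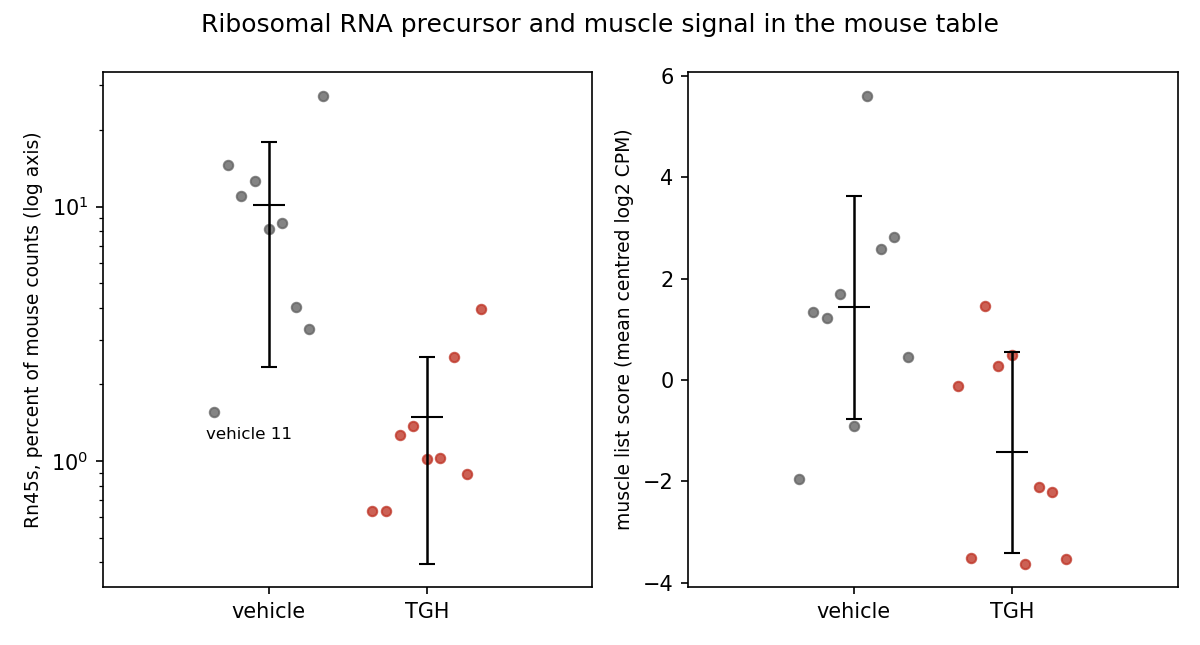
Rn45s as percent of mouse counts (left, log axis) and skeletal muscle list score (right, mean centred log2 CPM) per library, with the mean and SD of the 9 libraries of each arm. Rn45s averaged 10.1% in vehicle and 1.48% in TGH, and vehicle 11, at 1.56%, lies among the TGH libraries.

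The arms also differed in depth. Human counts averaged 24004100 in TGH and 15619468 in vehicle (n = 9 each, exact permutation p = 0.000946, adjusted over 7 measures 0.00331), and the 10 top mouse genes took 9.80 ± 1.38% of mouse counts in TGH and 16.8 ± 7.45% in vehicle (exact permutation p = 0.00276, adjusted 0.00643). The share of mouse counts in all counts was 17.5 ± 3.98% with TGH and 20.4 ± 4.41% with vehicle, a difference of -2.91 percentage points that did not exceed the spread between tumours (exact permutation p = 0.161). Ribosomal protein genes took 6.91 ± 1.73% of human counts in TGH and 7.60 ± 2.58% in vehicle (exact permutation p = 0.524). The mouse total (p = 0.0623), the mouse ribosomal protein share (p = 0.808) and the share of the 10 top human genes (p = 0.626) did not differ in exact permutation tests. Vehicle 16 and 19 also stood apart in the human table. On its first 2 principal components, the main axes of variation, they lay 117 and 162 from the centre, against at most 39.8 elsewhere. With counts thinned to equal depth all 22 called human genes named here still passed (edgeR).

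Tumour and host changes were set side by side over 9916 genes with the same symbol. SLC2A1 and P4HA2 were called higher in both tables. Across genes the fold changes correlated with a Pearson r of 0.21 and a Spearman rho of 0.25, genes not being independent replicates, and 59.8% had the same sign. Over 99 random splits of the same tumours the mean r was 0.177 (SD 0.0850). For the lists present in both tables, the change in tumour minus the change in host was -0.07 for hypoxia (exact permutation p = 0.523) and -0.06 for glycolysis (p = 0.509). Of the 7 lists compared in this way none differed between the compartments, the lowest adjusted p being 0.411, for oxidative phosphorylation, by exact permutation.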

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

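Several tests were chosen after the results were seen. They were those of the 3 vehicle libraries with the fewest human counts, of the Rn45s level and of muscle against other host cells. Those of RPPH1, of DNA replication against histones and of the leak a gene would need were chosen then as well. The test of genes with little leak was chosen after the first leak test. The readings of RPPH1 and of the leak needed were made stricter, from decided to open, after their values were seen.

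In 18 of 248 groups of 9 libraries 1 library stood far from the rest of its arm, where chance would give about 12.4 such cases. In vehicle 16, ARRDC4 (log2 CPM -3.32) had 0 counts, which allows up to 0.289 CPM, against 86 to 209 counts in the other 8 vehicle libraries, and TXNIP was the lowest of the arm at 7.17. Other vehicle values that stood apart were PADI3 at -3.32 in vehicle 19 and SLC2A4 at -3.32 in vehicle 18, both with 0 counts, ZNF587 at 6.05 in vehicle 11, mouse Slc16a3 at 2.84 and Col1a1 at 11.24 in vehicle 19 and Ccr7 at 2.13 in vehicle 16. In TGH 4, HK2 was high at 7.52 and P4HA1 at 8.99. HMOX1 was high in TGH 10 at 5.68, Loxl2 low in TGH 6 at 8.57 and Ptprb low in TGH 7 at 5.84, all as log2 CPM. The mouse hypoxia score was low in TGH 6 at -0.022, and the score of pericytes and smooth muscle low in TGH 2 at -0.25. The 10 top mouse genes took 33.2% of mouse counts in vehicle 20 and 13.1% in TGH 10, and Rn45s took 27.3% in vehicle 20.

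The hypoxia and glycolysis lists were higher with TGH in both tables. Without vehicle 16, 18 and 19 the largest exact p was 0.0140, which argues against those 3 libraries as the whole source. With the Rn45s level as a covariate the largest permutation p was 0.00511. Rn45s largely followed the arm (1.48% of mouse counts in TGH, 10.1% in vehicle), and the human glycolysis difference grew from 0.42 to 0.78 under it. That adjustment therefore cannot exclude a difference in library make-up linked to rRNA. Reads of human genes counted as mouse stay open for the mouse lists: at the highest leak seen among epithelial genes, 1.76% for Cdh1, they could reach 13.2% of the mouse counts of the median list gene, above the 10% set as a limit beforehand, and the epithelial genes read in the mouse table rose in score by 0.66 (exact p = 0.0149), as much as the hypoxia list. To give its mouse difference the median gene would need a leak of 3.01% of its human reads even with no leak in vehicle (lower quartile 2.13%, and above 1.76% in 33 of 43 genes), which argues against a leak at the epithelial rate as the whole source but leaves open a higher one, not measured for these genes. The 8 list genes where a leak of 1.76% gives under 5%, such as Lox and Slc2a3, also differed by 0.66 (exact p = 4.11e-05, the smallest possible) and would need leaks of 6.04% or more (median 27.8%), which argues against leakage as the whole source for those genes unless they leak far more than epithelial genes. Mouse reads counted as human were not measured for the genes of the human lists. Mouse stroma markers read in the human table rose in score by 0.43 (exact permutation p = 0.0333). In TGH, however, P4HA1 had 81164 human and 7982 mouse counts, and LDHA 360149 and 27303. Their rises of 0.66 and 0.50 log2 would need more reads than those mouse counts. Of the 43 genes, only Lox, Ppfia4 and Slc2a3 had more mouse than human counts in TGH. This argues against mouse reads as the whole source for list genes with as few mouse counts as P4HA1 and LDHA. A part stays open. An effect of TGH remains a hypothesis, since depth and library make-up differed with the arm.

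Skeletal muscle genes were lower with TGH. The score difference without vehicle 16, 18 and 19 was -1.74, against -2.86 with all libraries, but its exact p was 0.0895, so muscle tissue in those 3 pieces and a difference across the arm cannot be told apart with the libraries left. The muscle score fell relative to the macrophage and fibroblast scores (larger exact p = 0.00995). A fall of all host cells alike would leave such scores unchanged, because they are scaled within the mouse table, so whether one occurred was not tested.

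Rn45s and RPPH1 were called lower with TGH, and the histone list was called lower by camera but not with fry, an estimated correlation or thinned counts. RPPH1 rose with Rn45s within the vehicle arm (Pearson r = 0.701, exact p = 0.0352, Spearman rho = 0.567, exact p = 0.121) and within the TGH arm (r = 0.742, exact p = 0.0224, rho = 0.600, exact p = 0.0968), but without the 2 libraries farthest in Rn45s r was -0.0530 in vehicle (without 11 and 20) and 0.352 in TGH (without 10 and 7), so both relations lean on those libraries. The histone score followed Rn45s in the TGH arm (r = 0.904, exact p = 0.000361, rho = 0.917, and 0.767 without the 2 farthest libraries), while in the vehicle arm r was 0.633 (exact p = 0.0666). A difference in rRNA depletion or library make-up and an effect of TGH cannot be told apart here. In the vehicle arm the relation of RPPH1 leaned on 2 libraries and that of the histones did not pass. The DNA replication score itself hardly changed (-0.0069, exact permutation p = 0.953). Its change did not differ from that of the histones beyond the spread (0.36, exact p = 0.0879), so lower DNA replication stays open for the histones. Vehicle 11 lay nearer to TGH than to vehicle in 25 of the 31 human and 5 of the 8 mouse genes called lower (at most 5 and 3 in another vehicle library), but in 3 of the 30 human and 1 of the 10 mouse genes called higher (up to 10 and 6), so in most of the genes called lower it sat with TGH 1 to 10. A preparation of libraries 1 to 11 apart from 12 to 20 could give this and part of the 31 lower calls, but the labels give no batch and vehicle 11 alone would part it from the arm, so it stays open and was not tested.

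Other splits of the 18 libraries, 100 with the real one included, show how far chance can be excluded. Chance was an unlikely source of the 30 human genes higher and the 31 lower. For these, 2 splits gave as many in 1 direction, the real one included, the highest other being 750. The same held for the 10 mouse genes higher and 8 lower (1 split each, the highest other 0). It held too for the hypoxia score in human (1 split, 0.61 against 0.51) and mouse (1 split, 0.68 against 0.50). The split with 750 calls, 1469 in both directions, put 7 of the 9 vehicle libraries, 16, 18 and 19 among them, on 1 side with TGH 6 and 10. The few other random splits that parted the arms as far had 0 human calls. Nearness to the real split was thus not enough for such calls, but whether it added to the 1469 was not tested. Of 14 random splits that kept vehicle 16, 18 and 19 together, 1 had any human call. So many calls point to a structure of the samples, whose source was not tested. Chance was not excluded for the number of lists called, 3 in human (76 splits, up to 14 lists) and 10 in mouse (14 splits, up to 11), nor for the correlation of human and mouse fold changes (28 splits, 0.21 against up to 0.44).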

How the results depend on the processing

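The Rn45s covariate, thinning and the fit without vehicle 16, 18 and 19 were chosen after the data were seen. Those 3 libraries had the fewest human counts, while vehicle 20 had the fewest mouse counts. Causes of the shifts below were not tested unless fewer libraries or genes explain them. The human hypoxia and glycolysis lists and the mouse hypoxia, glycolysis, matrix and muscle lists were called in the same direction under every alternative in which single lists were recomputed except the estimated correlation, which left 0 human lists (3 at unadjusted p below 0.05) and 1 mouse list, hypoxia. In simulations at the depth and edgeR dispersions of each table, edgeR recovered 31.3% of 1.5-fold changes in human and 14.9% in mouse. Of the DESeq2 calls there 12.8% and 8.64% were unchanged genes, against 4.68% and 3.50% with edgeR, whose own dispersions had been used.

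Human genes higher numbered 30, and 143 with DESeq2, 117 with weighted voom, 53 with the mouse share, 104 with 1 surrogate variable and 3 with Rn45s, of which 1 was among the 30. Human genes lower numbered 31, and 227 with DESeq2, 119 with weighted voom, 19 with voom, 20 without a filter, 15 with human plus mouse library size, 159 with the surrogate variable, 96 without the 3 libraries (23 of the 31 kept) and 0 with Rn45s. Increases made up 49.2% of human calls, 38.6% with DESeq2, 27.3% without the 3 libraries, 100% with Rn45s, and from 30.4% (vehicle 11) to 66.7% (TGH 2) with 1 library left out. Mouse genes higher numbered 10, and 62 with DESeq2, 16 with voom, 25 with weighted voom, 3 with human plus mouse library size, 3 with the mouse share and 6 without the 3 libraries, while the 10 with Rn45s shared 2 with the original 10. Mouse genes lower numbered 8, and 80 with DESeq2, 13 with weighted voom, 20 with human plus mouse library size, 3 with the mouse share, 4 without the 3 libraries and 2 with Rn45s. Increases made up 55.6% of mouse calls, 43.7% with DESeq2 (3 increases against 20 decreases with human plus mouse library size), 69.6% and 65.8% with voom without and with weights, 83.3% with Rn45s, and from 18.2% (vehicle 11) to 100% (TGH 4 or 9) with 1 library left out. Without Rn45s and Lars2 in the table, also chosen after the data were seen, 3 mouse genes were higher and 1 lower: 12 of the 16 named calls left were lost at an adjusted p of 0.0527 or 0.0534, with fold changes 0.986 to 1.02 times the original. Human lists called numbered 3, and 5 with the mouse share, 10 without the 3 libraries and 5 with Rn45s.

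With 1 library left out, human genes higher ranged from 6 (TGH 4) to 43 (TGH 10), with fewer than 20 also without TGH 2, 3, 5, 7 or 9 or vehicle 14, 15 or 16. Human genes lower ranged from 4 (TGH 2 or TGH 4) to 78 (vehicle 11), which kept all 31, and fell to 17 or fewer also without TGH 1, 3, 5 or 9 or vehicle 12, 14, 15 or 16. Mouse genes higher ranged from 1 to 19 (vehicle 12 or 20) and lower from 0 (TGH 4 or 9, with 657 and 628 at unadjusted p below 0.05) to 18 (vehicle 11), each moved by every single library. Human lists ranged from 3 to 5 (TGH 7), mouse lists from 8 to 11, and the mouse share difference from -3.77 to -1.82 points. The difference in the share of the 10 top human genes ranged from -0.310 (TGH 10) to 0.0485 points (vehicle 19), and that of mouse ribosomal protein from -0.485 (vehicle 13) to 0.327 (vehicle 19), with 0.0220 without vehicle 16.

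Single values changed direction as follows, none of them called in either fit unless said. With Rn45s, the histone list, called lower without it, had a mean of -0.16 but pointed up in camera, where it was not called (adjusted p = 0.906). Also with Rn45s, CYP1B1 stood at -0.64, ARRDC4 at -0.16, DDIT3 at 0.049, Adgre1 at -0.063 and Cd3e at 1.85. The called genes Lars2 and Rn45s stood at 0.31 and 0.072 there, Rn45s being its own covariate. With human plus mouse library size Pdpn stood at -0.021 and Adgre1 at -0.037. Without the 3 libraries the mouse oxidative phosphorylation and ribosomal protein lists turned to 0.11 and 0.17. Both were called upward there and downward with all libraries. S100a8 turned to 0.32, Cycs to 0.048 and Ndufb8 to 0.13.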

Other observations

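Beyond the genes above, several genes were called higher in the tumour cells by edgeR. FBXO32, a ubiquitin ligase subunit known from muscle atrophy, rose by 1.06 ± 0.14 (adjusted p = 0.00276), from 32.5 ± 9.14 to 67.9 ± 8.10 CPM, and PALMD, a paralemmin relative, by 1.04 ± 0.15. The inflammatory cytokine IL1B rose by 1.04 ± 0.22, while its list was not called (camera adjusted p = 0.550, 1 member called over all genes and 2 adjusted over the list alone). The Notch ligand JAG1 rose by 0.73 ± 0.15, ERRFI1, a feedback inhibitor of EGFR signalling, by 0.81 ± 0.15, and the protease inhibitor CSTA by 0.93 ± 0.18. Enzymes of glycogen use, PYGL (0.67 ± 0.15) and PGM1 (0.43 ± 0.10), rose as well. These genes were chosen after their values were seen. In the host, Il1b (0.64 ± 0.20), Il1a (0.71 ± 0.21) and Ptgs2 (0.95 ± 0.28) passed adjusted over the list of inflammatory cytokines alone but not over all genes, and that list was not called (camera adjusted p = 0.0939).

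Whether tumour and host hypoxia scores go together within an arm was set as a hypothesis before it was tested. They did in the vehicle arm (Pearson r = 0.801, exact permutation p = 0.0232, Spearman rho = 0.867, exact p = 0.00451, and r = 0.842 without vehicle 16 and 19, the farthest from the median). In the TGH arm r was 0.682 (exact permutation p = 0.0396) and rho 0.633 (exact p = 0.0760), and r was 0.501 without TGH 4 and 6, so that relation leaned on those libraries. Adjusted over the 6 correlations computed, the Pearson p was 0.0464 in vehicle and 0.0475 in TGH. The relation may reflect a state shared by tumour and host cells of a piece, or reads divided imperfectly between the species.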
